A study of Mus musculus with 2 samples.

How the data were processed

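Gene expression was compared between 2 strains of mouse induced pluripotent stem cells, 20D17 and 38C2, on 2 two-colour microarrays. Per the labels, each array was hybridised with 1 RNA from strain 20D17 carrying Cy3 and 1 RNA from strain 38C2 carrying Cy5, and the RNAs of the 2 arrays came from independently grown and harvested cultures. Total RNA was extracted with Trizol, amplified and dye-coupled with an amino allyl kit following the 3D-Gene and Ambion protocols, per the labels' protocols. Both arrays had the same dye orientation, so a probe's bias toward one dye repeats on both arrays and cannot be told apart from a difference between the strains.

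The deposited value table holds 1 number per probe and array, with 2 decimals, for 23473 probes. How the authors made these values is not given in the sources used here, so they were treated as a score on a log scale. Positive and negative numbers in each column and a median of 0.00 on both arrays mark them as log ratios centred on the median of each array. The log base stayed unknown, and so did the direction, that is, whether a positive number means more signal from 20D17 or from 38C2. All values are therefore given in deposited units with their sign, and no sign is assigned to a strain. Folds are stated for log2 and for natural logs.

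The other deposited tables, 1 per array, list the intensities of 1750 blank spots in each dye, sorted within each dye. Per the file headers and summary lines, the authors marked the 88 lowest and the 88 highest blank spots of each dye as outliers and took the mean, the SD and the mean plus 2 SD of the 1574 left. Recomputing these from the listed spots gave the same numbers within 1e-08. Signals of the probe spots were not analysed here, so the depth behind a ratio is unknown and the number of arrays limits the precision.

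The test planned before the data were examined was kept: limma 3.58.1 in R 4.3.3, a fit of the mean ratio over the 2 arrays with moderated variances, a two-sided test against 0 and Benjamini-Hochberg adjustment at 0.05 over the 15772 probes with a value on both arrays. The ratio pairs the 2 RNAs of an array. The fit has 1 residual degree of freedom per probe, to which the moderation added 3.91. The value table took the place of scanner signals, as planned for that case. The plan also asked for its scale and direction to be worked out against scanner values, which was not done. The planned filter, a probe signal above the blank mean plus 2 SD, needed probe signals. Probes with a value on both arrays were kept in its place. The deposited values were used with no further background correction or normalization. A rule of size counted probes at 1 or more, or at -1 or less, on both arrays, which is 2-fold if the values are log2. Correlations are across probes, which are not independent replicates. Bootstrap intervals (2000 draws of probes, 500 for the ratio of spreads) and exact binomial (Clopper-Pearson) intervals are at the 95% level and cover the drawing of probes only.

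The planned accounts of named genes and of 29 gene lists (594 genes, from pluripotency and cardiac regulators to markers of other cell types) were not carried out. None of the 23473 probe IDs matched an identifier in the reference gene table used here (GRCm38.p6, 49997 genes), and the files do not pair the IDs with genes. The rule for named genes passes over unnamed probes, so it named none. In their place, 2 probe IDs per sign are given, those with the largest value of the smaller of their 2 absolute ratios.

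The fit was tested on simulated data: 20 simulations of 15772 probes with variances drawn from the fitted prior, and 200 probes changed in each. Among probes changed by 4 deposited units 63.4% were called, among those changed by 2 units 0.672%, and among those changed by 1 unit 0 of 1340. Of all 921 calls, 8.14% were on unchanged probes, above the adjusted threshold of 0.05. These shares hold for the number and sizes of the changes put in and for variances that do not depend on the mean ratio. They do not give the power of the test in the real data.

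Alternatives were leaving out each array, no filter on probes with 1 value, a variance trend, an adjusted p of 0.10 and a limit of 1.5-fold, all planned, and equal spread of the arrays, quantile normalization and a natural-log reading, added after seeing the data.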

Results

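The study set a strain of mouse induced pluripotent stem cells with low potency, 20D17, against a strain with normal potency, 38C2; its title names the capacity to form cardiomyocytes. Induced pluripotent stem cells are somatic cells returned to an embryonic-like state by introduced transcription factors, and per the labels both strains received Oct3/4, Sox2, c-Myc and Klf4. The cells were grown on gelatin without feeder cells and harvested after several passages. Each strain contributed 2 biological replicates, and each of the 2 arrays carried 1 replicate of each strain. The 20D17 RNA was always in the Cy3 channel and the 38C2 RNA always in the Cy5 channel.

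Array 1 gave a ratio for 17250 of the 23473 probes and array 2 for 17016, leaving 26.5% and 27.5% of the probes empty. A ratio was listed on both arrays for 15772 probes, on array 1 alone for 1478, on array 2 alone for 1244 and on neither for 4979. If the arrays had left probes empty independently of one another, 1712 probes would have been empty on both. Empty probes were more frequent among IDs beginning with M400 (34.3% on array 1 and 35.7% on array 2) than among those beginning with M300 (24.8% and 25.9%) or M200 (19.6% and 20.1%).

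Blank spots, which carry no probe and give the background, were brighter and more variable in Cy3 than in Cy5 on both arrays. On array 1 the background was 111 ± 3.27 (SD, n = 1574 spots) in the Cy3 channel of 20D17 and 96.8 ± 0.536 (SD, n = 1574 spots) in the Cy5 channel of 38C2. On array 2 it was 112 ± 3.46 in Cy3 and 97.2 ± 0.515 in Cy5 (SD, n = 1574 spots each). The authors' limit, the mean plus 2 SD, was 117.7 in Cy3 and 97.9 in Cy5 on array 1, and 119.0 in Cy3 and 98.2 in Cy5 on array 2. It therefore stood 6.54 and 6.92 units above the mean background in Cy3 and 1.07 and 1.03 units above it in Cy5. With the spots that the authors set aside counted in, 7.37% of the 1750 blank spots exceeded the Cy3 limit on either array (exact 95% interval 6.19 to 8.70%). In Cy5, 8.51% did so on array 1 (7.25 to 9.92%) and 8.11% on array 2 (6.88 to 9.49%). The limits came from these same spots with the 88 highest left out, so part of each share is built in. The intervals take the limits as fixed, and the shares do not measure false detection of probes.

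The main comparison asked which probes differed between the 2 strains. Its largest reproducible ratios lay far outside the spread of the bulk of the probes, on both the positive and the negative side. Probe M400002945 had a ratio of 4.43 on array 1 and 4.58 on array 2, a mean of 4.505 ± 0.106 deposited units (SD, n = 2 arrays). That is a difference of 22.7-fold between the 2 channels if the values are log2 and of 90.5-fold if they are natural logs. Probe M200012714 had ratios of 5.83 and 4.11, a mean of 4.97 ± 1.22 (SD, n = 2), or 31.3-fold in log2 and 144-fold in natural logs. On the negative side, probe M200013640 had ratios of -3.41 and -4.44, a mean of -3.925 ± 0.728 (SD, n = 2), or 15.2-fold in log2 and 50.7-fold in natural logs. Probe M200003604 had ratios of -3.44 and -3.03, a mean of -3.235 ± 0.290 (SD, n = 2), or 9.42-fold in log2 and 25.4-fold in natural logs. Opposite signs stand for opposite directions between the 2 channels. Each strain kept its dye on both arrays, so a probe's bias toward 1 dye could give such repeated ratios as well. The named probes were picked for the size of these same ratios. Which strain was higher for which sign is not settled by the sources used here, and neither is the gene each probe measures.

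None of these differences passed limma's test as planned for the main comparison. In it, 0 of the 15772 probes reached an adjusted p under 0.05, and the lowest adjusted p was 0.393, which all 4 of these probes shared. Without adjustment, limma's p was 4.18e-05 for M400002945, 2.07e-04 for M200012714, 2.08e-04 for M200013640 and 2.37e-04 for M200003604. An unadjusted p under 0.05 was reached by 1897 probes, 12.0% of those tested, where a rate of 0.05 would give 788.6. Of the 1897 probes, 1283 were positive and 614 negative. With the signs of array 2 turned, 134 probes (0.850%) reached it. Ratios shared by the arrays add to the spread in that control, so its count is no exact baseline either. Shared dye bias would raise the 1897 in the same way as a strain difference. In simulations of the same size, limma called 63.4% of probes changed by 4 deposited units and 0.672% of those changed by 2 units. These shares depend on how many large changes were put in, because the adjustment's cut-off moves with that number. That number is unknown for the real data, so the shares do not give the test's power there. The simulated variances also did not depend on the mean ratio. In the data, the MAD of the difference between arrays was 0.593 for means from -2 to -1 and 1.56 above 2. A second fit in limma, which let the variance follow the mean ratio, called 317 probes, 316 of them negative. Its single positive call was M200012714 (adjusted p = 0.0499, limma). It also turned the balance of signs at an unadjusted p under 0.05, to 24 positive and 2077 negative probes. With no probe signals, the trend in this second fit ran along the same ratio that was tested. It called negative probes with means up to -1.03, but not M200013640 (adjusted p = 0.891, limma) or M200003604 (adjusted p = 0.685, limma). Its calls and signs therefore cannot be separated from the fitted trend.

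By size, 493 probes had a ratio of 1 or more on both arrays and 202 had a ratio of -1 or less on both, 695 in all. Independent arrays with the same numbers of large ratios would share 232 positive and 44.9 negative probes, so the observed numbers were 2.12 and 4.50 times higher. Ratios of this size with opposite signs on the 2 arrays were found for 72 probes, against 212 for independent arrays. The positive share, 70.9% of the 695, held for a limit read as log2; with the values read as natural logs a 2-fold limit kept 1657 probes, 60.9% of them positive. Of the 2824 probes at 1 or more on array 1, 17.5% were also at 1 or more on array 2 (exact 95% interval 16.1 to 18.9%). Of the 946 probes at -1 or less on array 1, 21.4% were so on array 2 (18.8 to 24.1%). Taken from array 2, 38.0% of its 1296 probes at 1 or more were so on array 1 (35.4 to 40.7%). Of its 749 probes at -1 or less, 27.0% were (23.8 to 30.3%), so the order was the opposite. Each share depends on how many large ratios the other array held, which on array 1 was 2824 positive and 946 negative. The shares therefore do not compare repeatability between the signs.

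The replicate arrays agreed in part. Across the 15772 probes the ratios of the arrays correlated with Pearson's r = 0.350 (bootstrap 95% interval 0.335 to 0.366) and Spearman's rho = 0.351. The sign was the same for 9738 probes and opposite for 5831, or 62.5% the same, where 50.1% would be the same by chance; for 203 probes at least 1 ratio was 0.00. The difference between the arrays had an SD of 0.953, or 0.674 per array if the noise were equal on both. The arrays' unequal SDs do not bear out that equality, so 0.674 is no estimate for either array alone. Array 1 had the wider distribution over these probes, with an SD of 0.941 against 0.693. On both arrays the upper tail was longer: the 5th and 95th percentiles were -1.04 and 2.00 on array 1 and -0.953 and 1.35 on array 2, over all probes with a value. The correlation was of similar size within each ID series, with r = 0.350 for M200, 0.339 for M300 and 0.355 for M400.

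**Figure D1:**
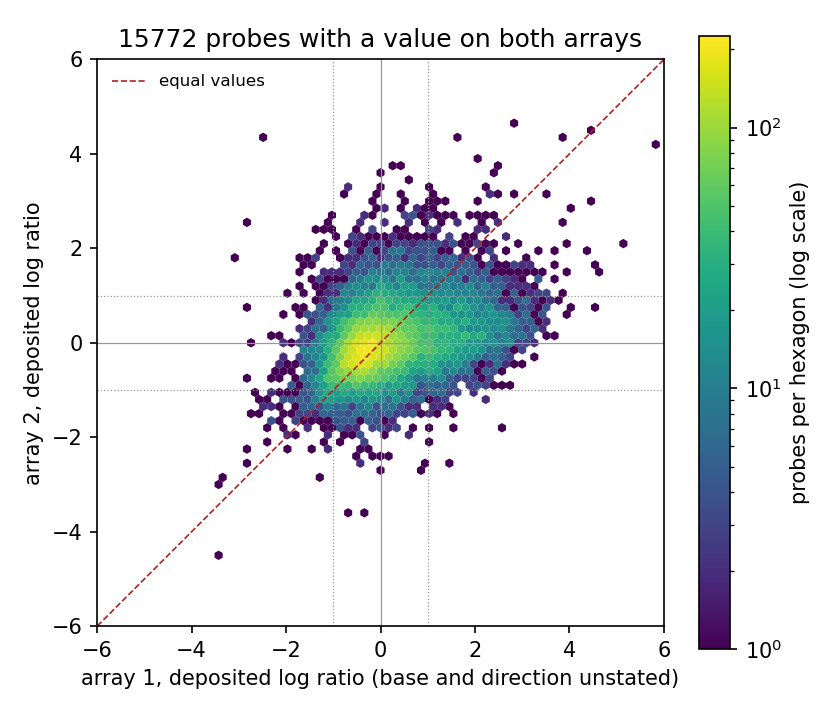
Deposited log ratio of each of the 15772 probes on array 1 (horizontal axis) and array 2 (vertical axis), in deposited units; colour gives the number of probes per hexagon on a log scale, dotted lines mark -1 and 1 and the dashed line equal values. The cloud rises along the diagonal (r = 0.350) and extends farther to the right, where array 1 is at 1 or more for 2824 probes and array 2 for 1296.

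Probes with a ratio on a single array had a higher median ratio than those with a ratio on both. It was 0.38 on array 1, against -0.03 for probes measured on both, a difference of 0.41 (bootstrap 95% interval 0.35 to 0.46). On array 2 the medians were 0.59 and -0.03, a difference of 0.62 (0.56 to 0.68). The ratio was positive for 66.5% of the probes measured on array 1 alone and for 79.1% of those measured on array 2 alone, against 48.2% and 47.4% of the probes measured on both.

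**Figure D2:**
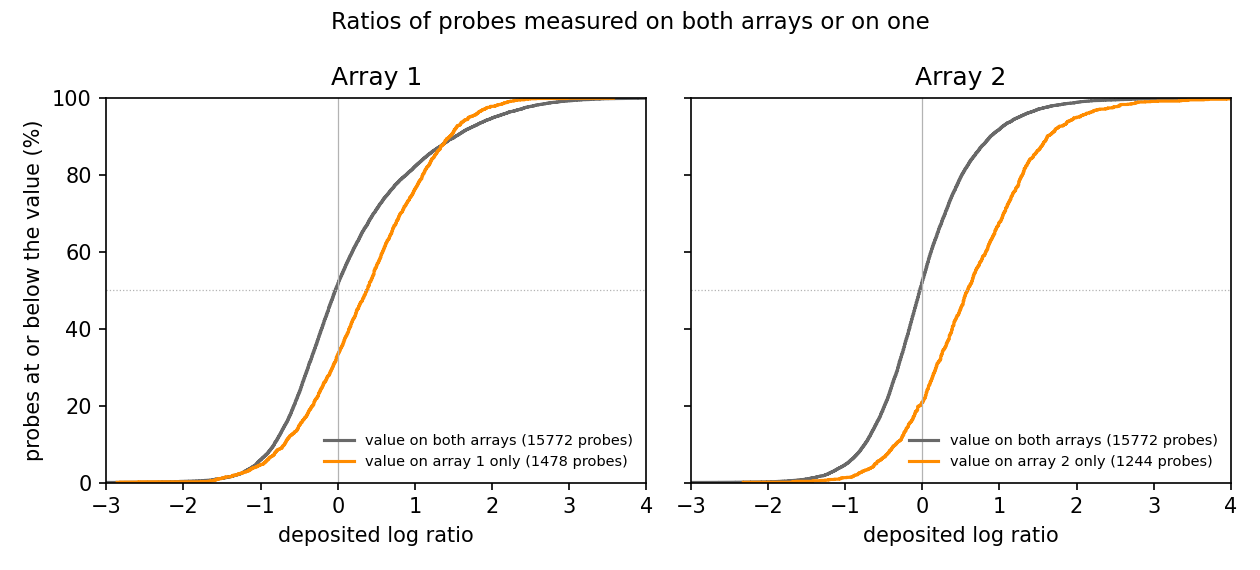
Cumulative percent of probes (vertical axis) at or below each deposited log ratio (horizontal axis, deposited units) on array 1 (left) and array 2 (right), for the 15772 probes with a value on both arrays (grey) and the 1478 or 1244 with a value on that array alone (orange). At 50% the orange curve lies 0.41 to the right of the grey one on array 1 and 0.62 on array 2.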

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

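The absence of calls held in limma with no filter (18494 probes, lowest adjusted p 0.404), at an adjusted p under 0.10, with equal spread of the arrays (lowest adjusted p 0.263) and with quantile normalization (0.285), these last 2 settings and the natural-log reading being chosen after seeing the data. The probes added with no filter have a value on 1 array only, so their p rests on the variances of other probes alone. The variance trend alone gave calls, 317. With no probe signals that trend runs along the ratio itself: all 316 negative calls had a mean between -1.83 and -1.03, and 0 of the 14 probes at -2 or less were called. M200012714 was the positive call (adjusted p = 0.0499, limma). The count of 695 by size was 708 with equal spread, 801 with quantile normalization, 2271 at 1.5-fold (57.2% positive) and 1657 with natural logs. Leaving out 1 array gave 2045 probes without array 1 and 3770 without array 2, since a single array has to pass; those are values with no test. The correlation was 0.353 after quantile normalization. The means of the 4 named probes moved by less than their SD in all 8 scaling alternatives. Not run, as they need probe signals or gene names: other background corrections, loess, Aquantile, the upper 50% by signal, unpaired channels and the gene list tests. Median centring is already in the values. No unpaired fit of the channels was made, so the within-array ratio is the only pairing used.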

Other observations

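The tests of detection limits and of shared dye bias were chosen after the results were seen; those of the ID series, the ID order and the value distributions were fixed before their results were seen. No biological explanation was tested for these patterns, and the difference between the strains stays open throughout.

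The arrays correlated across probes (r = 0.350), which a difference between the strains would give. A trend along the probe IDs was tested as another source: after a running median in ID order was taken off each array, r was 0.343, which argues against it. Dye bias shared by the arrays remains open, since 0 arrays had swapped dyes, and it cannot be told apart from the strain difference.

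Probes measured on a single array had a higher median ratio than those measured on both, though on array 1 fewer of them reached 2 or more (2.17% against 5.28%). The makeup of the ID series, which differ in how many probes were empty, did not account for it: within each series and array the difference of medians was 0.385 or more, with bootstrap intervals above 0. A candidate explanation is unequal detection limits of the 2 dyes. In intensity units, the Cy3 limit stood 6.11 times as far above the mean background as the Cy5 limit on array 1 and 6.72 times on array 2. These heights were not set against amounts of RNA, so they do not show unequal limits in RNA. Whether these limits decided which probes were left empty is not given. If they did, probes near the limits might keep a ratio more often when it leans to 1 dye. How bright these probes were was not measured here, and without probe signals and the direction of the ratio this stays open.

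The arrays differed less from one another for negative than for positive mean ratios. The difference between arrays had a MAD of 1.29 for the 1644 probes with a mean of 1 or more and 0.593 for the 428 with a mean of -1 or less, a ratio of 2.17 (bootstrap interval 1.78 to 2.49). Of the large ratios on array 2, 38.0% of the positive and 27.0% of the negative ones were as large on array 1. These shares do not compare repeatability, because array 1 held 2824 ratios at 1 or more and 946 at -1 or less. Against independent arrays, the number shared was 2.12 times higher on the positive side and 4.50 times higher on the negative side. The difference between the arrays' value distributions does not account for the unequal MADs as a whole, since their ratio was 2.62 (2.17 to 2.99) after quantile normalization. Both arrays had the longer upper tail, which quantile normalization keeps, so this test cannot speak to that shared tail. Other explanations were not tested.

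For means between 1 and 2, array 1 exceeded array 2 by a median of 1.13 over 1501 probes. The share of probes at 2 or more on array 1 had an exact interval of 1.49 to 3.04% among those measured on it alone and 4.93 to 5.64% among those measured on both. On array 2 the shares were 5.14% (3.98 to 6.52%) and 1.15% (0.987 to 1.33%).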
